A study of Mus musculus with 4 samples.

How the data were processed

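The series holds 4 libraries of CD4+ T cells from the spleen of Smarta1 mice, enriched on magnetic beads and sorted by flow cytometry, and cultured with dendritic cells, peptide, IL-4 and antibody to interferon gamma, per the labels' protocols. Libraries were made from 100 ng of RNA with a stranded poly-A kit (TruSeq) and sequenced as single ends on a NextSeq instrument with 150 cycles, per the labels' protocols. The labels put 2 libraries in the vehicle group and 2 in the GW9662 group.

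The deposited table lists 22880 genes. Its signal values are, per the file headers, the authors' normalized count per gene and library, that is, reads per gene divided by a factor for each library. The authors' log2 ratio and their shrunken log2 change compare vehicle with GW9662, per the file headers, so that their sign is the opposite of the one used here. The authors' p-value and false discovery rate (FDR) per gene are deposited beside them. The GC fraction and the length in bases of each gene model are given by the authors, per the file headers. STAR, edgeR and the build GRCm38 are named in the submitters' processing notes, while their versions, the counter, its strand setting and the annotation release are not given in the sources used here. The file's columns spell the antagonist GW9962, and they were matched to the labels by treatment and number. Symbols of 27 genes had turned into dates and were looked up by Ensembl ID. Coordinates are those of GENCODE M21 on GRCm38, in which 22570 IDs (98.6%) were found. No gene, locus or sample beyond this table was analysed here.

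Every value of up to 100 reads was a whole multiple of what 1 read was worth in its library (100% within 0.1 reads), so that reads could be recovered, and larger values, kept to 4 significant digits, give reads to that precision. A count of 0 allows up to 1.16, 2.87, 2.19 and 0.974 normalized counts in vehicle 1, vehicle 2, GW9662 1 and GW9662 2, taking 3 reads as the limit. Counting intervals (95%) and these limits cover counting error only. No pair of libraries agreed within sampling noise: the chi-square per gene was 218 for the vehicle pair and 37.9 for the GW9662 pair. Across genes, which are not independent replicates, the log2 values correlated with r = 0.960 in the vehicle pair, 0.992 in the GW9662 pair and 0.966 between vehicle 1 and GW9662 2. In a principal component analysis the leading components held 71.1% and 24.9% of the variance.

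The design fixed before the data were examined gave edgeR's quasi-likelihood test for whole counts and limma for normalized values. As the table held normalized values, the test was limma with a mean-variance trend on log2(normalized count + 1), over the 11522 genes with a mean of at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. Unless another test or setting is named with it, each adjusted p of a gene in the report comes from this limma model, and is two-sided. Of 33 gene lists fixed before the data were examined, the 26 with at least 5 tested members entered camera with a preset correlation of 0.01, adjusted over lists, with camera on an estimated correlation beside it. Fry was run too, which compares a list with no change and not with other genes. None of the 9 lists called with the preset correlation was called with an estimated one. With an estimated correlation camera takes its degrees of freedom from the few libraries and not from the genes, which by itself weakens every list. The estimate was -0.048 for the T helper 2 list and 0.0082 for the p53 list, below the preset 0.01. Camera's unadjusted p still rose from 0.0023 to 0.080 and from 2.2e-04 to 0.065. Loss of a call there alone therefore does not show that correlated members made it. Gene ontology terms of 10 to 500 tested genes were tested with one-sided Fisher's exact tests for each direction, against tested genes with a term of the same branch, adjusted over terms and directions. The table holds term IDs only, and the names used are general knowledge.

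Genes were named by a rule fixed before the data were examined. It took the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 50 and groups that did not overlap, without unnamed gene models, pseudogenes and receptor segments. It added Pparg, Il4, Il5, Il13, Il1rl1, Gata3, Il17rb, Ifng, Tbx21 and Cd4. From each list of a biological theme it took up to 4 called genes by p, and from each list of other cells up to 3 by mean. Some genes that the rule took are not reported here. Arg1, Fcgr3, Cntnap1, Aldh1a1, Iltifb, Fut7, Rxra, the members named of the lists on retinoic acid and the genes named for ontology terms fall outside it and were named after their values were seen.

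The alternatives were other pseudocounts, filters, scalings, tests on the recovered reads (edgeR, limma-voom and DESeq2), thresholds, the authors' deposited table, the replicate number as a block and leaving out each library, where the lone library of a group is assumed to vary like the other group. That assumption is not met by these pairs, since the SD of the log2 difference was 0.688 in the vehicle pair and 0.290 in the GW9662 pair. Without a vehicle library the adjusted p of a gene is therefore likely too small. Without a GW9662 library it rests on the wider vehicle pair alone. Removal of each library's trend with gene length and GC (loess with a span of 0.5) and a crossed block were added after seeing the data. In simulated data 200 sampled genes among 11522 were changed, and the 34 mitosis genes were raised 4-fold as well. Of the sampled genes, the limma test recovered 30.3% of 66 changed 2-fold, 97.0% of 66 changed 4-fold and 100% of 64 changed 16-fold. Of its calls, those of mitosis genes included, 6.74% were false, and with no change it called 0 genes. Counts were drawn gene by gene with the same dispersion in every library. They lacked the wider spread of the vehicle pair and any trend with gene length and GC, so these rates may not hold for the real data. A length and GC trend was then added to vehicle 2 and removed. Of the true calls made without that trend, 98.9% were called after its removal. Calls in all numbered 193 without the trend, 164 with it left in and 189 after its removal. The added trend was linear and its size was not matched to that of the real vehicle 2.

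Of the tests of technical explanations, 3 were set aside after their results were known. A comparison of GW9662 1 with vehicle 2, each against the mean of the other 3 libraries, gave -0.192 and was replaced because that mean holds vehicle 2 and so pushes the others the opposite way. The share of called genes in which vehicle 1 lay apart from both GW9662 libraries by at least 0.5 of the fold change was 100%, and was dropped because it ran on genes chosen for being called. Random thinning of vehicle 1 to the reads of vehicle 2 closed 0.0490% of their gap by gene length, and was dropped because random loss keeps each gene's expected share, so that the outcome was fixed. The analysis used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.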

Results

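The libraries held poly-A RNA of CD4+ T cells sorted from the spleen of Smarta1 mice, whose T cells carry a transgenic receptor for the gp61 peptide of lymphocytic choriomeningitis virus. The cells were cultured for 4 days with dendritic cells, 100 nM gp61, 100 ng/ml IL-4 and 20 µg/ml antibody to interferon gamma, a setting that favours the T helper 2 (Th2) fate. For 2 libraries the culture held GW9662, an antagonist of the nuclear receptor PPARγ, and for the other 2 its DMSO vehicle, and the dose of GW9662 was not given in the sources used here. The question was how blocking PPARγ during this coculture alters the T cell transcriptome. Values are the authors' normalized read counts per gene, given as mean ± SD with n = 2 libraries per group, and differences are log2 fold changes of GW9662 minus vehicle on the log2(normalized count + 1) scale, which understates changes of low genes. The reads recovered from the values came to 40852277 and 18019151 for vehicle 1 and 2, and to 21044047 and 47766349 for GW9662 1 and 2. Nothing in the labels says that replicates came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.

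With GW9662 the transcript of the receptor itself and those of Il5 and Il1rl1 in the Th2 programme fell, while Il4, Il13 and Gata3 did not pass the test. The transcript of Il5, the cytokine that drives eosinophil production, fell from 292 ± 17.3 to 8.61 ± 0.241 normalized counts (log2 fold change -4.93, SE 0.267, adjusted p = 0.0015). Il1rl1, which encodes the receptor for IL-33, fell from 950.2 ± 361.8 to 98.5 ± 10.8 (log2 fold change -3.21, SE 0.324, adjusted p = 0.0059). Pparg itself fell from 1093 ± 91.2 to 169.9 ± 16.8 (log2 fold change -2.68, SE 0.236, adjusted p = 0.0047). Il9, a cytokine gene linked to mast cell growth, rose from 53.8 ± 22.6 to 345.5 ± 11.6 (log2 fold change 2.73, SE 0.340, adjusted p = 0.014). Il4 had 442.2 ± 102.7 and 379.0 ± 13.5 normalized counts in vehicle and GW9662 (log2 fold change -0.20, SE 0.262), and Il13 had 829.9 ± 140.6 and 774.2 ± 19.4 (log2 fold change -0.09, SE 0.244). Neither passed the test (adjusted p = 0.80 and 0.90), and neither did Gata3, the lineage factor of Th2 cells (log2 fold change -0.22, SE 0.233, adjusted p = 0.78). Il17rb, which encodes a receptor subunit for IL-25, did not pass over 4 libraries (log2 fold change -0.83, SE 0.238, adjusted p = 0.19 in limma). Its log2 fold change was -0.73 without vehicle 1 and -0.94 without vehicle 2. It passed with the length and GC trend removed (adjusted p = 0.028 in limma), but not in the authors' deposited table (FDR 0.11). Of the 20 tested members of the Th2 list, 3 were lower, 1 was higher and 16 did not pass, and adjusted over the list alone 5 were lower and 1 was higher. The median log2 fold change of the list was -0.30 (-0.20 without vehicle 2) and camera called it lower (adjusted p = 0.0077), with adjusted p = 0.69 with an estimated correlation. Fry's directional test, which compares the list with no change and not with other genes, gave adjusted p = 0.033.

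In the T helper 17 (Th17) programme 5 genes rose. Il22 went from 1.63 ± 0.961 to 267.4 ± 58.3 normalized counts (log2 fold change 6.70, SE 0.39, adjusted p = 0.0016), and Il17f from 1.92 ± 0.0127 to 156.4 ± 22.5 (log2 fold change 5.75, SE 0.317, adjusted p = 0.0015). Il17a rose to a far lower level, from 2.50 ± 0.831 to 19.5 ± 4.56 (log2 fold change 2.55, SE 0.409, adjusted p = 0.032), and Il21 rose from 252.6 ± 82.9 to 957.0 ± 258.8 (log2 fold change 1.93, SE 0.333, adjusted p = 0.042). Of 9 tested members 5 passed over all genes, all of them higher. Adjusted over the list alone 7 were higher and 1 was lower. Its median was 1.93 and camera called the list higher (adjusted p = 4.6e-06), with adjusted p = 0.69 with an estimated correlation. Il17a did not pass without GW9662 1 (adjusted p = 0.12), nor Il21 without GW9662 2 (adjusted p = 0.14). Il22 has a near-identical copy, Iltifb, so the split of reads between the 2 genes is uncertain. Camera did not call the list of the T helper 1 (Th1) fate. Of 14 tested members of it only Stat4, which encodes the signal transducer of IL-12, passed, and it was lower (log2 fold change -1.33, SE 0.233, adjusted p = 0.045), a call lost without GW9662 1 or GW9662 2 (adjusted p = 0.66 and 0.35). The list's median was 0.24 (adjusted p = 0.38 by camera), with 2 members higher and 2 lower adjusted over the list alone. Tbx21, the Th1 lineage factor gene, had 25.99 ± 5.12 and 8.45 ± 0.471 normalized counts and did not pass over 4 libraries (log2 fold change -1.50, SE 0.342, adjusted p = 0.10 in limma). Its log2 fold change was -1.70 without vehicle 1 and -1.31 without vehicle 2. It passed with the length and GC trend removed (adjusted p = 0.039 in limma) and in the authors' deposited table (FDR 0.0050). By edgeR's quasi-likelihood test and DESeq2 it did not pass (adjusted p = 0.086 and 0.17). Ifng was below the filter, with 6 reads over both vehicle and 7 over both GW9662 libraries.

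**Figure D1:**
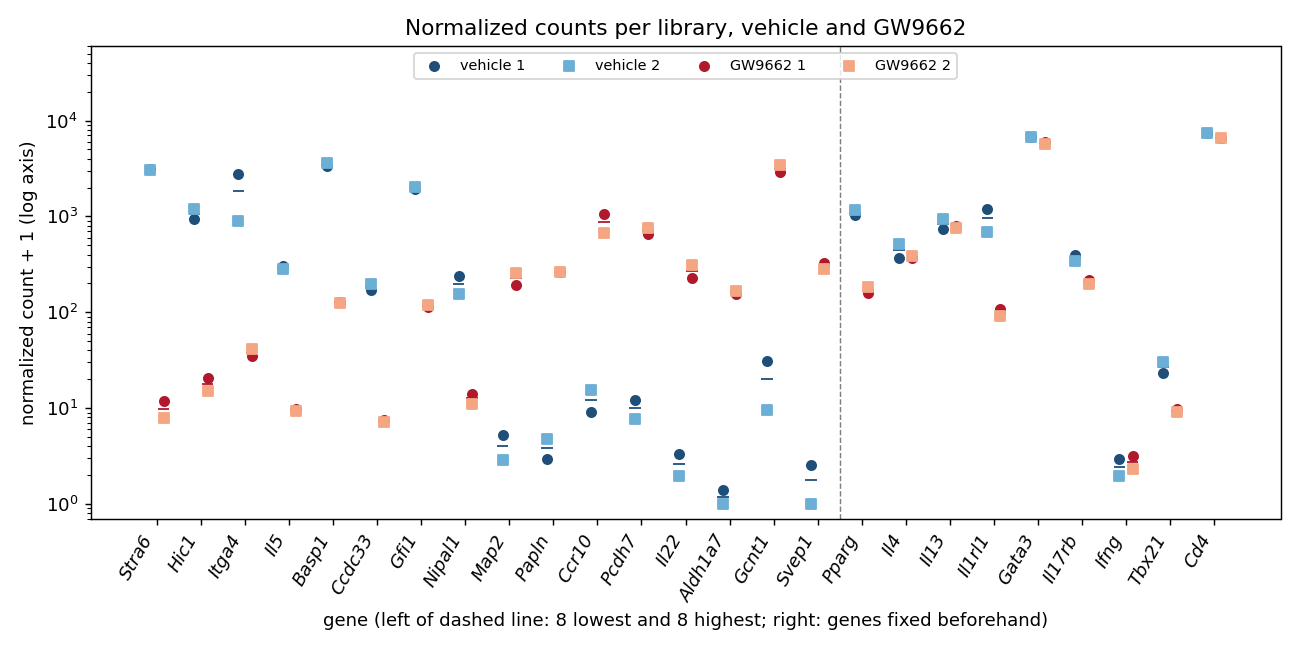
Normalized count + 1 per library on a log axis, for the 8 lowest and 8 highest log2 fold changes among named called genes with a mean of at least 50 (left of the dashed line) and the genes fixed beforehand (right), with vehicle in blue, GW9662 in red and orange, circles for replicate 1, squares for replicate 2 and short lines for group means. Stra6 sits at 3136 and 3073 normalized counts with vehicle and at 11.0 and 6.82 with GW9662.

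Across all genes, 291 of 11522 tested passed an adjusted p of 0.05 in limma, 175 higher and 116 lower with GW9662. All 291 differed by at least 1 on the log2 scale and 206 by at least 2. In each of the 291 the GW9662 libraries lay on one side of the vehicle libraries, as they did in 4721 (41.0%) of all genes tested, against 33.3% by chance. Among called genes with a mean of at least 50 the largest fall was that of Stra6, which encodes a membrane receptor for retinol uptake (ENSMUSG00000032327, chromosome 9, 58063788 to 58153996 on GRCm38, plus strand). Stra6 dropped from 3104.5 ± 44.5 to 8.89 ± 2.94 normalized counts (log2 fold change -8.33, SE 0.290, adjusted p = 6.8e-04), with 11349 vehicle and 36 GW9662 reads. Hic1, a transcriptional repressor gene (ENSMUSG00000043099, chromosome 11, 75164565 to 75169519, minus strand), dropped from 1062 ± 171 to 16.9 ± 4.10 (log2 fold change -5.91, SE 0.287). Itga4, the alpha 4 integrin gene (ENSMUSG00000027009, chromosome 2, 79255426 to 79333123, plus strand), dropped from 1832 ± 1338 to 36.9 ± 4.66 (log2 fold change -5.38, SE 0.520), and its vehicle libraries differed, at 2778 and 886 normalized counts. Basp1 (-4.76), Ccdc33 (-4.64), Gfi1, a transcriptional repressor gene active in Th2 cells (-4.09), and Nipal1 (-3.95) completed the lower end by log2 fold change after Il5, among genes with a mean of at least 50. Ccdc33 lies on the opposite strand and overlaps Stra6 over 55036 bases, and with the counter not given in the sources used here its reads cannot be told apart from those of Stra6.

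Svep1, an adhesion protein gene (ENSMUSG00000028369, chromosome 4, 58042442 to 58206859, minus strand), had the highest log2 fold change of all 291 called genes on the log2(normalized count + 1) scale, and rose from 0.772 ± 1.09 to 304.3 ± 35.2 normalized counts (log2 fold change 7.58, SE 0.490, adjusted p = 0.0020), with 4 vehicle reads in all. The order depends on that scale, since Aldh1a7 exceeded Svep1 by edgeR (log2 fold change 8.93 against 8.09) and Gcnt1 exceeded it in the authors' table (6.98 against 5.71). Gcnt1, an enzyme that branches O-linked glycans (ENSMUSG00000038843, chromosome 19, 17326141 to 17372844, minus strand), went from 19.1 ± 14.9 to 3152 ± 394 (log2 fold change 7.52, SE 0.528, adjusted p = 0.0026). Aldh1a7, an aldehyde dehydrogenase gene, had 1 vehicle read and 723 GW9662 reads, a ratio of 592 after scaling, with a 95% counting interval of 106 to 23399. Its relative Aldh1a1, named here after its values were seen, was listed at 0 in both vehicle libraries and at 28.5 and 21.4 in the GW9662 libraries, and the division of reads between these paralogs is uncertain. Pcdh7 (6.18), the chemokine receptor gene Ccr10 (6.16), Papln (6.13) and Map2 (5.84) followed by log2 fold change after Il22, with adjusted p from 0.0015 to 0.0021. Ccr10 lies within Cntnap1 on the opposite strand, and Cntnap1 also rose (log2 fold change 4.38), so their reads are likewise uncertain. The count of 291 became 1201 without vehicle 2 and 5298 without vehicle 1, and 735 once each library's trend with gene length and GC content was removed, an alternative chosen after seeing the data that kept 287 of the 291. The counts without a vehicle library take their spread from the GW9662 pair alone (SD of the log2 difference 0.290, against 0.688 in the vehicle pair). A false discovery rate under 0.05 was given to 846 genes in the authors' deposited table, among them all 291.

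Among genes of T cell residence, memory and regulation, single members passed while camera called none of the lists. Itgae, the CD103 integrin gene, rose from 119.4 ± 27.0 to 2002 ± 204 normalized counts (log2 fold change 4.07, SE 0.265, adjusted p = 0.0020). In the same regulatory T cell list Gpr83 (-2.44) and Izumo1r, the folate receptor 4 gene (-1.86), fell, and the other 8 of 11 did not pass (median 0.13, and -0.23 without vehicle 2, 2 higher and 2 lower adjusted over the list alone). Btla (2.64) and Cd200 (2.36), both genes of inhibitory surface molecules, rose with Il21 among 9 follicular helper genes (median 0.71, 5 higher and 3 lower adjusted over the list alone). Camera did not call that list (adjusted p = 0.21), but did without vehicle 2 (adjusted p = 0.0039) and without GW9662 1 (adjusted p = 0.020). Tcf7, a transcription factor gene of naive and memory cells, rose from 604.3 ± 38.7 to 1672 ± 58.0 (log2 fold change 1.47), and of 12 tested naive and central memory genes 2 passed, both higher. The list had 3 members higher and 3 lower adjusted over the list alone (median 0.32, and 0.08 without vehicle 2). Havcr2, which encodes TIM-3, rose (log2 fold change 1.97) with Btla among 11 inhibitory receptor genes (median -0.25, and -0.08 without vehicle 2, 3 higher and 1 lower adjusted over the list alone). Gzmb, the granzyme B gene, fell from 50590.0 ± 8146 to 15925 ± 247 (log2 fold change -1.66) as 1 of 7 cytotoxic genes (median 0.17, 1 higher and 1 lower adjusted over the list alone). Tnfrsf9, the 4-1BB gene, fell (log2 fold change -1.78) as 1 of 15 activation genes (median 0.52, adjusted p = 0.081 by camera, 3 higher and 1 lower adjusted over the list alone). The fixed list of T cell chemokines and chemokine receptors holds neither Ccr10 nor Ccl22, and none of its 12 tested members passed in limma over all genes, with 1 higher and 2 lower adjusted over the list alone (median 0.06). Izumo1r, Tcf7, Gzmb and Tnfrsf9 did not pass without GW9662 1 or without GW9662 2, where the spread comes from the wider vehicle pair alone. In these 2 settings in turn, the log2 fold change was -1.898 and -1.824 for Izumo1r and 1.503 and 1.432 for Tcf7. It was -1.674 and -1.642 for Gzmb, and -1.86 and -1.69 for Tnfrsf9.

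Camera called the list of interferon-stimulated genes higher with the preset correlation (adjusted p = 0.0012), but not with an estimated correlation (adjusted p = 0.72). Gbp2, a guanylate-binding protein gene, rose from 210.8 ± 34.7 to 1330.0 ± 233.3 normalized counts (log2 fold change 2.65, SE 0.263, adjusted p = 0.0059), and Zbp1, a nucleic acid sensor gene, from 717.5 ± 180.7 to 2334 ± 15.6 (log2 fold change 1.72, SE 0.267, adjusted p = 0.028). The other 26 of 28 tested members did not pass, and 4 were higher adjusted over the list alone. The median was 0.54. The list's call was lost without vehicle 1 (adjusted p = 0.13) and without GW9662 2 (adjusted p = 0.053), and that of Zbp1 without GW9662 1 or GW9662 2 (adjusted p = 0.12 and 0.13). The p53 response list was called higher with a median of 0.36 (adjusted p = 0.0014, with adjusted p = 0.69 with an estimated correlation), although none of its 14 tested members passed in limma over all genes and 4 were higher adjusted over the list alone. Its adjusted p was 0.053 without GW9662 2.

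Camera called the hypoxia, glycolysis, ATF4 and oxidative phosphorylation lists lower with the preset correlation, and none of them with an estimated correlation (adjusted p from 0.72 to 0.87). None of 17 hypoxia response genes passed over all genes or over the list alone, yet 15 lay below 0 with a median of -0.55, and camera called the list (adjusted p = 0.0014, with adjusted p = 0.72 with an estimated correlation). The call was lost without GW9662 1 (adjusted p = 0.056). Of 22 glycolysis genes 20 lay below 0 (median -0.21, adjusted p = 0.025, with adjusted p = 0.85 with an estimated correlation). Slc2a3, which encodes the glucose transporter GLUT3, was the member that passed over all genes and over the list alone, and it fell from 16290.0 ± 2107 to 5025 ± 305 normalized counts (log2 fold change -1.69, SE 0.248, adjusted p = 0.024). That call was lost without GW9662 1 or GW9662 2 (adjusted p = 0.29 and 0.20). None of 26 genes of the ATF4 and amino acid response passed over all genes or over the list alone (median -0.35, adjusted p = 0.0077, with adjusted p = 0.85 with an estimated correlation), and the list's call was lost without vehicle 2 (adjusted p = 0.29) and without GW9662 2 (adjusted p = 0.11). None of 39 nuclear-encoded oxidative phosphorylation genes passed over all genes or over the list alone, and 37 lay below 0 (median -0.29, adjusted p = 0.0070, with adjusted p = 0.87 with an estimated correlation). Vehicle 2 stood apart from the other libraries by gene length, with short genes higher. Its deviation from the mean of the other 3 libraries differed by 1.28 on the log2 scale between the shortest and longest eighth of genes. The same difference was -0.49, -0.25 and -0.51 in vehicle 1, GW9662 1 and GW9662 2. Their reference means hold vehicle 2, which pushes these values the opposite way. Without vehicle 2 the medians of oxidative phosphorylation and glycolysis were 0.07 and -0.02 (adjusted p = 0.43 for each), and with the length and GC trend removed neither was called (adjusted p = 0.47 and 0.14). Without GW9662 2 they were not called either (adjusted p = 0.19 and 0.26), nor was glycolysis without GW9662 1 (adjusted p = 0.088).

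**Figure D2:**
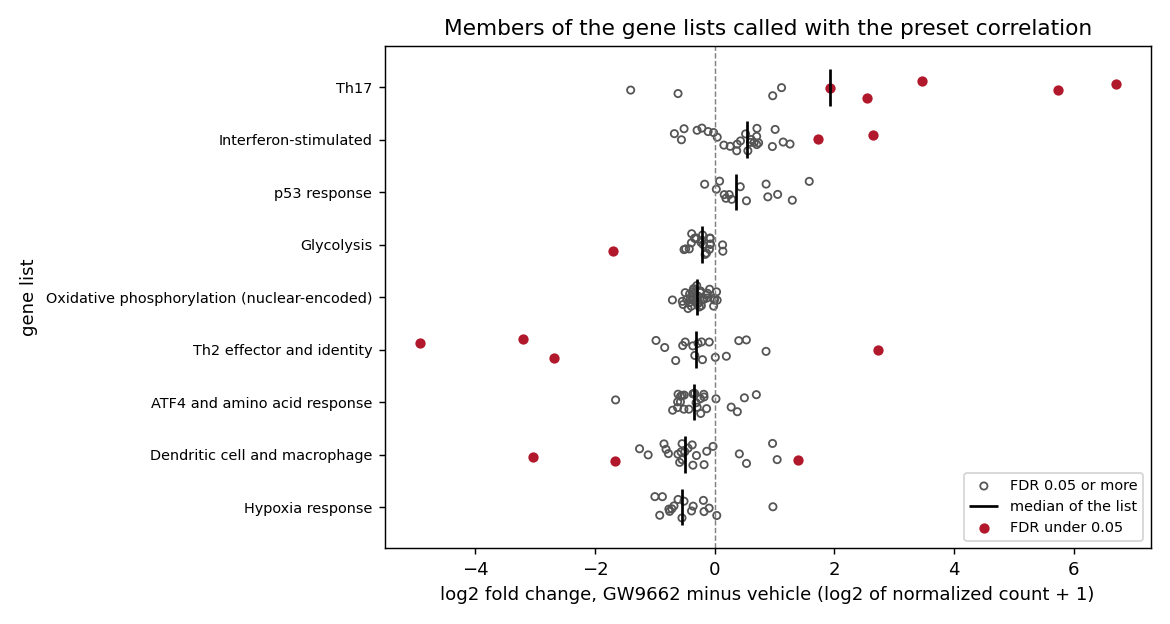
Log2 fold change (GW9662 minus vehicle, log2 of normalized count + 1) of each tested member of the 9 lists that camera called with the preset correlation. Filled points passed an adjusted p of 0.05 over all genes, open points did not, vertical bars are list medians, and the vertical scatter within a list carries no value. Th17 members reach 6.70, while the medians of the 6 lower lists lie between -0.55 and -0.21.

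**Figure D3:**
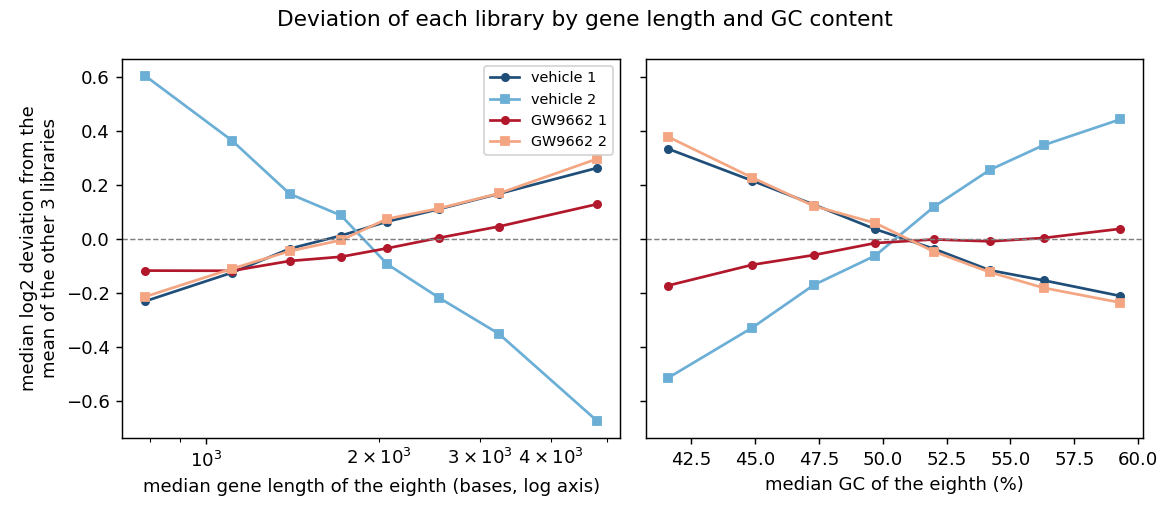
Median log2 deviation of each library from the mean of the other 3, over eighths of the tested genes ordered by gene length (left, log axis in bases) or GC content (right, %). Vehicle 2 falls from 0.60 in the shortest eighth to -0.67 in the longest.

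Camera did not call the list of lipid genes under known PPAR control. Fabp4, a fatty acid binding protein gene, rose from 6.9975 ± 2.26 to 113.6 ± 9.12 normalized counts (log2 fold change 3.87, SE 0.335, adjusted p = 0.0047), and Plin2, a lipid droplet coat gene, fell from 988.4 ± 265.4 to 316.7 ± 18.7 (log2 fold change -1.61, SE 0.274, adjusted p = 0.039). The call of Plin2 was lost without GW9662 1 or GW9662 2 (adjusted p = 0.14 and 0.24). The other 22 of 24 PPAR target and fatty acid oxidation genes did not pass (median -0.09, 1 higher and 2 lower adjusted over the list alone, adjusted p = 0.62 by camera). In limma none of 11 LXR targets (median -0.18), 30 cholesterol and fatty acid synthesis genes (median 0.04), 34 DNA replication genes (median -0.08), 34 mitosis genes (median 0.03) or 19 unfolded protein response genes (median -0.20) passed over all genes or over the list alone. Osgin1, an oxidative stress gene, fell from 103.1 ± 14.9 to 16.9 ± 6.05 (log2 fold change -2.57), and the other 20 of 21 tested NRF2 and glutathione genes did not pass over all genes or over the list alone (median 0.02, and 0.22 without vehicle 2).

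Genes typical of dendritic cells and macrophages were read in these libraries, and which cells their transcripts came from was not tested. Of 25 tested dendritic cell and macrophage genes, Arg1 (-3.03) and Fcgr3 (-1.66) were lower and Ccl22, a chemokine gene, was higher (log2 fold change 1.39, from 642.3 ± 97.9 to 1682 ± 115 normalized counts), with 2 higher and 3 lower adjusted over the list alone. The median was -0.50 and camera called the list lower (adjusted p = 0.0077, with adjusted p = 0.85 with an estimated correlation). Without vehicle 2 the median was -0.14 (adjusted p = 0.58), and with the length and GC trend removed the list was not called (adjusted p = 0.13). Among its most abundant members, Cst3 had 2455 ± 1208 and 1587 ± 221 normalized counts (log2 fold change -0.54) and H2-Ab1 2157 ± 860 and 960.3 ± 97.2 (log2 fold change -1.11). Neither passed in limma over 4 libraries. H2-Ab1 passed with the length and GC trend removed (adjusted p = 0.029 in limma) and by DESeq2 (adjusted p = 0.038). It also passed in the authors' deposited table (FDR 0.035), but not by edgeR's quasi-likelihood test (adjusted p = 0.18). Without vehicle 1 and without vehicle 2 in turn, the log2 fold change was -1.53 and -0.69 for H2-Ab1. For Cst3 it was -1.07 and -0.02, so that its fall vanished without vehicle 2. Ccl22 was not called without GW9662 1 or GW9662 2 (adjusted p = 0.32 and 0.56). Cd4 had 7410 ± 121 and 6542 ± 21.2 normalized counts (log2 fold change -0.18, adjusted p = 0.80), and none of the 15 CD4 T cell genes passed over all genes (median -0.18, and -0.01 without vehicle 2, 1 higher adjusted over the list alone).

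Other cell types had few tested genes. Pax5, a B cell factor gene, rose from 1.73 ± 0.260 to 36.7 ± 1.89 normalized counts (log2 fold change 3.79), while Ighm (0.09) and Cd79b (-2.07) did not pass over 4 libraries (median of the 3 tested 0.09, 1 higher and 1 lower adjusted over the list alone). The log2 fold change of Cd79b was -2.44 without vehicle 1, -1.70 without vehicle 2 and -2.44 without GW9662 1. Cd79b passed by DESeq2 (adjusted p = 0.016) and in the authors' deposited table (FDR 1.9e-04), but not by edgeR's quasi-likelihood test (adjusted p = 0.066). Of the granulocyte and mast cell genes, Cpa3 fell (log2 fold change -3.12) and Kit rose (log2 fold change 3.06), the 2 of 19 that were tested (median -0.03), and Siglecf was near 1 normalized count in every library. Pdgfrb fell (log2 fold change -2.01), while Pecam1 (-0.86) and Col1a1 (0.03) did not pass among the 3 tested stromal and endothelial genes (median -0.86, 2 lower adjusted over the list alone). The call of Pdgfrb was lost without GW9662 2, where its log2 fold change was -1.83. The log2 fold change of Pecam1 was -0.82 without vehicle 1 and -0.89 without vehicle 2. Pecam1 passed with the length and GC trend removed (adjusted p = 0.019 in limma), but not in the authors' deposited table (FDR 0.12). Cd8b1 (-0.24), the NK cell genes Klra7 (0.24) and Cd244 (-0.36, median -0.06) and the erythroid gene Epor (-1.66) did not pass over 4 libraries by log2 fold change. Epor had a log2 fold change of -2.30 without vehicle 1 and -1.02 without vehicle 2. It passed in the authors' deposited table (FDR 0.014), but not by DESeq2 (adjusted p = 0.14). Cd8a, Eomes, Hba-a1 and Klf1 were below the filter. The 4 tested members of the sex-linked list, all Y-linked, had a median of 0.27 (-0.34 without vehicle 2) and none passed. The 7 tested mitochondrially encoded genes had a median of -0.01 (-0.33 without vehicle 2) and none passed over 4 libraries, with 1.15%, 0.653%, 0.734% and 1.28% of reads in vehicle 1, vehicle 2, GW9662 1 and GW9662 2, where ribosomal protein genes took 5.84%, 10.6%, 6.73% and 5.92%.

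Called genes were enriched in 20 combinations of gene ontology term and direction (one-sided Fisher's exact test, adjusted p under 0.05). The count was 1 with no filter on low values, 3 with a mean of at least 50, 169 without vehicle 1, 103 without vehicle 2 and 8 without GW9662 2. Extracellular space genes were enriched in both directions, with 24 of 449 higher (adjusted p = 3.2e-04) and 16 of 449 lower (adjusted p = 0.0085). So were cytokine activity genes, with 8 of 73 higher (adjusted p = 0.0085), among them Csf1, Il9 and Tnfsf4, and 6 of 73 lower (adjusted p = 0.037), among them Il5. Higher genes also included 13 of 207 cell adhesion genes (adjusted p = 0.0093), among them Itgae, Selp and Vcan. Lower genes included 9 of 82 extracellular matrix genes (adjusted p = 3.2e-04), among them Fn1, Col4a1 and Col4a2. They also held 3 of 11 genes of the major histocompatibility complex class I (adjusted p = 0.044), namely H2-Q6, H2-Q7 and H2-Q10, near-identical paralogs whose reads may be split uncertainly. Genes are not independent replicates in these tests. The median, the mean and camera's direction differed in sign for 9 lists, none of them called: cytotoxic, inhibitory receptor, PPAR target, LXR target, cholesterol synthesis, mitosis, chemokine, CD4 T cell and mitochondrially encoded genes. Without vehicle 2 the median changed sign for the regulatory T cell, LXR target, mitosis, chemokine, oxidative phosphorylation, NK cell, granulocyte and sex-linked lists.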

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

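The trend removal and the crossed block were chosen after seeing the data, and the other alternatives before. Of 45 called genes that the naming rule took, 33 kept their direction and call in every setting and 12 did not. Of 16 that it took and that were tested but not called, 9 stayed so in every setting and 7 did not. Of 9 lists called, 0 kept the call in every setting, since none was called with an estimated correlation, a setting that few libraries weaken for every list. Of 17 lists tested but not called, 6 stayed so and 11 did not, with fry's mixed test among the settings. The count of 291 changed genes (175 higher, 116 lower) was 167 (97 and 70) with a mean of at least 50, which tests fewer genes, and 110 (69 and 41) at an FDR of 0.01, a stricter threshold. It was 735 (409 and 326) with the length and GC trend removed, 831 (484 and 347) with edgeR's exact test, 554 (313 and 241) with DESeq2 and 846 (501 and 345) in the authors' deposited table. Without 1 library it ranged from 229 to 5298 (139 to 2755 higher, 80 to 2543 lower). All 291 kept their sign without each library in turn, an outcome fixed in advance because their groups do not overlap. Fewer of them passed without a GW9662 library than without a vehicle library. Without a GW9662 library the spread comes from the wider vehicle pair alone, and without a vehicle library from the GW9662 pair alone. The lost calls therefore cannot tell whether they rested on a single GW9662 library. Against 9 lists called, the count was 0 with an estimated correlation and 4 to 8 without 1 library. It was 1 by fry's directional test and 18 by its mixed test, which both compare a list with no change and not with other genes, so they ask other questions than camera. The median of oxidative phosphorylation ranged from -0.67 without vehicle 1 to 0.067 without vehicle 2, where it reversed. Against 20 ontology results there were 1 with no filter, 3 with a mean of at least 50, 8 with 50 reads in 2 libraries, 12 with library size only, 73 with the trend removed, 62 with the exact test, 11 with voom, 33 with DESeq2, 62 in the authors' deposited table and 8 to 169 without 1 library. Beyond the named constructions, the cause was not tested. No scaling moved the median of all genes by more than 0.1, and calls were 60.1% higher against at most 64.6% under another scaling. With 2 libraries per group, simulated 2-fold changes were mostly missed, and the depth of 18019151 reads in vehicle 2 limits genes near 0 there.

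The labels do not say whether same-numbered libraries were paired. Their deviations correlated across genes at -0.504 (-0.272 with the trend removed), which cannot decide it. With the number as a replicate block the count was 484 (300 higher, 184 lower), with 43 ontology results. With the crossed pairing it was 1258 (801 and 457), with 80 ontology results.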

Other observations

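The retinoic acid and skin homing lists, the depth tests of vehicle 2, the dendritic cell comparison and the trend removal were chosen after related results were seen. Fut7, a fucosyltransferase gene, was at 13.1 and 20.1 normalized counts in the vehicle libraries and at 255.3 and 206.1 in the GW9662 libraries (log2 fold change 3.74, adjusted p = 0.0046 in limma). Rxra, which encodes the partner receptor of PPARγ, rose as well (log2 fold change 1.75, adjusted p = 0.019 in limma). Because Fut7, Gcnt1 and Ccr10 were seen among the higher genes, 8 further genes of skin homing were tested as a list. None of the 7 tested members passed in limma, and the median was 0.50 (p = 0.18 by camera, 0.30 with an estimated correlation), a negative result.

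Vehicle 2 stood apart from the mean of the other 3 libraries, with higher values for short genes (shortest minus longest eighth 1.28) and lower values for genes of low GC (lowest minus highest eighth -0.96). Removing each library's trend with length and GC left 98.6% of the called genes called with their sign. These genes were chosen for being called, and removal also lowered the median SE from 0.282 to 0.173. The share kept therefore cannot decide whether the trend was the source of those calls. Their log2 fold changes were at least 1. By length, the median deviation of vehicle 2 ran from 0.60 in the shortest eighth to -0.67 in the longest. By GC, it ran from -0.51 in the lowest eighth to 0.44 in the highest. Medians of eighths do not bound single genes, and both trends can add up in a gene, so this cannot decide it either. Against the 2 deep libraries, the length difference of GW9662 1, of similar depth, was 0.128 times that of vehicle 2. For GC it was 0.503 times. This compares 1 library with 1, so it cannot decide whether something tied to depth had a share. Random loss of reads keeps each gene's expected share, so fewer reads by themselves would not give either trend. What set vehicle 2 apart stays open, RNA quality, library preparation and a biological difference included.

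The oxidative phosphorylation and hypoxia lists were both called lower, but differed in how far they rested on that trend. With it removed, the oxidative phosphorylation list kept 33.1% of its median, so the trend of vehicle 2 could account for most of its shift. The hypoxia list kept 88.9%, which argues against the trend there, and its adjusted p was 5.6e-04 with the trend removed. Its call was lost without GW9662 1 (adjusted p = 0.056) and with an estimated correlation (adjusted p = 0.72). An effect of GW9662 on hypoxia response genes stays a hypothesis.

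Stra6, Hic1 and Itga4, which had the lowest log2 fold changes of the named genes, are known to respond to retinoic acid. Of 12 further such genes, whose values had not been displayed when the list was written and of which Ccr9 is also in the fixed chemokine list, 6 were tested, with a median of -1.84 (p = 3.0e-05 by camera, 0.082 with an estimated correlation). Dhrs3 (-3.77), P2rx7 (-2.30) and Tgm2 (-1.75) fell by log2 fold change in limma, while Cd38 (-1.92), Itgb7 (-0.67) and Rarg (0.82) did not pass, so lower retinoic acid signalling with GW9662 may be a hypothesis to follow up. The dendritic cell and macrophage list had a median of -0.50 (-0.14 without vehicle 2) against -5.38 for Itga4, the smallest of the 3 falls. Its tested members ranged from -3.03 for Arg1 to 1.39 for Ccl22, so none fell as far as Itga4. Which cells these transcripts came from was not tested. The comparison therefore cannot decide whether fewer carried-over dendritic cells, or fewer of 1 kind, had a share in the 3 falls. Each fall kept at least 97.5% of its size with the trend removed, an outcome nearly fixed in advance for falls so much larger than the trend. Whether GW9662 acted on the T cells or on the dendritic cells of the culture was not tested.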
